A study of Mus musculus with 5 samples.

How the data were processed

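RNA sequencing measured gene expression in forelimb muscle tissue of C57BL/6 mouse embryos at embryonic day 15.5. There were 3 Noggin-deficient and 2 wild type samples, grouped by the genotype label. Per the labels' protocols, total RNA was isolated with the RNeasy Micro kit and checked on a Qubit fluorometer and a Bioanalyzer, and libraries were made with the KAPA stranded mRNA kit, amplified with 11 cycles of PCR and sequenced on an Illumina instrument. The labels do not say whether the samples were separate embryos, pools or litters, and give neither sex nor batch. Each p-value therefore measures only the spread between these samples, which may be technical.

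The deposited values are a non-negative expression signal, 1 value per gene and sample, normalized by the authors in a unit that neither the files nor the labels name. They are decimals, not read counts. Among 134 genes with a 0 in some library, the smallest non-zero value tended to be lower for longer transcripts (Spearman correlation -0.39). The submitters' processing notes name STAR 2.4.2a, DESeq2 without a version and the mouse build mm9, with no role for any of them. The counter, the annotation and the normalization are not given in the sources used here. The depth of the libraries is unknown, so no counting interval and no detection limit could be given, and a value of 0 is reported only as listed at 0.

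Each of the 5 tables held the same 4743 genes, in an order that followed the ratio of the group means almost exactly (Spearman correlation across genes -0.998). Only 2 genes lay within 0.2 log2 units of no change. Among genes with a mean of at least 1, the smallest rise was 0.36 and the smallest fall -0.24. The libraries of the groups did not overlap for 4658 genes (98.2%), where chance gives 20.0% for 3 samples against 2. The tables thus hold genes already selected for a difference between these same samples, by a rule not given in the sources used here. Adjusted p-values computed over them are not independent evidence of change, no background of unselected genes was used, and a list member without values was not analysed here.

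Genes were tested with limma 3.58.1 in R 4.3.3, by limma's moderated test with an intensity trend (limma-trend) on log2(value + 0.25), Noggin-deficient minus wild type, with no covariate. Genes with a value of at least 0.5 in at least 2 libraries were tested, which kept 3913 and left out 830. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are on the log2(value + pseudocount) scale, which understates the change of low genes. The plan made before the data were examined was a count model where the files held counts and limma on log values where they did not. The pseudocount and the minimum value were set once the unit was known. On simulated values for the 3913 genes, 34% of the genes changed 1.2-fold, 76% of those changed 1.5-fold, 90% of those changed 2-fold and 100% of those changed 4-fold were recovered, of 50 each, with 4 false calls among 154. The simulated spread was that of these selected genes, and 3713 of them were left unchanged. In the tables nearly every gene had been selected for a difference, so these rates do not describe the calls made here.

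The 26 gene lists were written before the data were examined, and 24 with at least 5 tested members were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over those lists. Camera sets a list against the other genes of these tables, which had themselves been selected. Camera with an estimated correlation, camera on ranks and limma's fry were run beside it. Fry asks whether the genes of a list move, on balance, one way, and compares them with no other genes. Adjusted p-values given for lists are camera's where no other test is named. Of 3913 tested genes 3836 were called, so a list whose members were all called says nothing particular about that list. The same holds for calls adjusted over the list alone. Further lists (liver, sympathetic neuron and chromaffin, basal epidermis, cornified envelope, mast cell, mitochondrial ribosomal protein, collagen, solute carrier and zinc finger genes) were written after values had been seen and were given no set test.

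Genes were named by a rule fixed before the data were examined. It took Nog, Id1, Id2, Id3, Smad6, Pax3, Pax7, Myf5, Myod1, Myog, Myh3 and Myh8 whatever their values. It added the 8 largest rises and the 8 largest falls among called genes with a mean of the group means of at least 5, no overlap between the groups' libraries and more than a predicted-gene identifier as a name. It also added the 2 members with the smallest p of each main list and the 1 with the smallest p of each other list. The minimum of 5 was planned for depth-scaled counts and was applied to the deposited unit. The rule took 68 genes, of which 61 had values. Id2, Pax3, Pax7, Myf5, Myod1, Myog and Myh8 were not analysed here. Other list members given as examples were chosen after their values were seen.

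Before the data were examined, the settings chosen for comparison were other pseudocounts, filters and scalings, a test against a 1.5-fold change, the replicate number as a block, leaving out each library, and other set tests. The scalings planned for counts were adapted to the listed genes. Median-of-ratios scaling takes most genes as unchanged, but the listed genes had been selected for a difference. Of them 2762 had a lower and 1976 a higher group mean in the Noggin-deficient samples. That scaling therefore moves the more common falls towards 0 whatever their cause. Centring on the middle of the gap between rises and falls, removal of the trend on transcript length, and Fisher's exact test of direction were added after seeing the data. Few listed genes lay near no change, so the fitted trend followed the more common direction among short and among long genes. Median log2 changes went from 0.4 in the shortest eighth of genes to -0.37 in the longest. Removing the trend thus moves a typical short gene that rose, or long gene that fell, towards 0 by construction. A call lost this way does not show that the change was an effect of length. Transcript length was the longest annotated transcript of a gene in the GENCODE annotation of GRCm38, found for 4447 listed genes (93.8%). This is another build than the submitters', so lengths were used as gene properties and no coordinates are given. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for summaries, permutation tests and plots.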

Results

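Gene expression was compared between forelimb muscle tissue of 3 Noggin-deficient and 2 wild type mouse embryo samples at E15.5. Noggin is a secreted protein that binds bone morphogenetic proteins (BMPs) and keeps them from their receptors. The series title places the comparison in the question of how the BMP and mechanical surroundings of muscle bear on the plasticity of the myogenic lineage. The listed values summed to 92210, 93695 and 92613 in the Noggin-deficient libraries and to 100792 and 102784 in the wild type libraries. Across the listed genes, log2 values correlated at r = 0.997 within each group and at r = 0.949 to 0.950 between the groups, over genes that are not independent replicates. The median coefficient of variation of genes with a mean from 20 to 100 was 2.31% among the Noggin-deficient and 1.7% among the wild type libraries. The listed genes had been selected for a difference between these groups. That lowers the correlation between the groups by construction and may favour genes with little spread within a group. These values therefore do not measure replicate quality or group separation over all genes. The number of reads behind each value is unknown.

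Nog, the gene of Noggin, had values of 0.49, 0.42 and 0.42 in the Noggin-deficient samples and 2 and 1.99 in the wild type samples, a log2 change of -1.70 (SE 0.092, limma adjusted p = 2.6e-06). The part of Nog altered by the mutation is not given in the sources used here. Most of the tested genes that respond to BMP signalling rose. Id1, a BMP-induced inhibitor of basic helix-loop-helix factors, went from 46.1 ± 1.28 (SD, n = 2) to 64.8 ± 0.503 (SD, n = 3), a log2 change of 0.49. Id3, of the same family, went from 70.5 ± 0.184 (SD, n = 2) to 97.8 ± 3.22 (SD, n = 3), a log2 change of 0.47, and Smad6, an inhibitory SMAD, from 4.18 ± 0.156 (SD, n = 2) to 6.14 ± 0.211 (SD, n = 3), a log2 change of 0.53.

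Of the 11 tested BMP response genes, 10 rose and 1, Gata3, fell, with a median log2 change of 0.53, and the same 11 passed when adjusted over the list alone. The list stood apart from the other listed genes (camera adjusted p = 0.00064, and adjusted p = 0.22 with an estimated correlation). The homeobox gene Msx1 rose by 1.86 and Hand2, a basic helix-loop-helix factor, by 1.06 on the log2 scale. Msx1 and Msx2 are also expressed in the distal limb, Hand1, Hand2 and Gata3 also in sympathetic neurons, and Id1, Id3, Smad6, Smad7 and Hey1 also in endothelium. Distal limb, neuronal and endothelial genes (median 0.49) were higher in the Noggin-deficient samples as well. Of 10 ligands, receptors and SMADs of the pathway, 2 rose and 8 fell (median -0.30, adjusted p = 0.45), Eng, a co-receptor that is also on the endothelial list, rising by 0.46 and Rgmb, another co-receptor, with a log2 change of -0.43. Under median-of-ratios scaling that median was -0.05 and the change of Rgmb -0.16, and after removal of the length trend both were -0.11. Of 6 extracellular antagonists 3 rose, among them Grem1 at 0.60, and 3 fell, Nog included. Their median was 0.06, their mean -0.13 and the camera direction up (adjusted p = 0.62), and the median turned to -0.24 with no filter on low values. All members of these lists passed adjusted over the list alone. After removal of the length trend, the changes of Id1 and Id3 were 0.21 and 0.23. Those of Smad6, Eng, Msx1 and Hand2 were 0.60, 0.60, 1.74 and 1.02. The median of the BMP response list was then 0.63 (camera adjusted p = 0.0028). Under median-of-ratios scaling the changes of Id1, Id3 and Eng were 0.76, 0.74 and 0.73. Against a 1.5-fold change, Id1, Id3, Smad6, Eng, Rgmb and Grem1 no longer passed (adjusted p = 1 each).

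**Figure D1:**
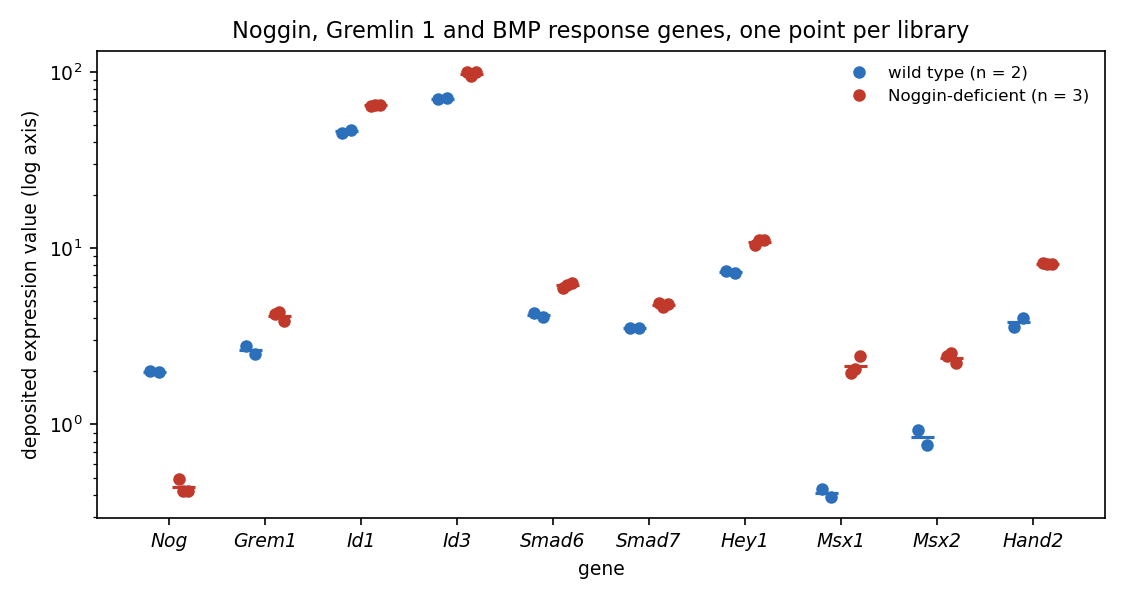
Deposited expression values on a log axis for Nog, Grem1 and 8 BMP response genes, with 1 point per library, blue for wild type (n = 2) and red for Noggin-deficient samples (n = 3), and short lines at the group means. Nog lies at 0.42 to 0.49 in the Noggin-deficient samples against 1.99 to 2 in wild type, while the other genes plotted are higher in each Noggin-deficient library than in either wild type library. The plotted genes were picked from the tested BMP response genes and antagonists. Gata3, Chrdl1 and Vwc2, which fell, are not plotted, nor are Smad9, Hand1, Sost and Kcp, which rose.

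Of 3913 genes tested, 3836 were called, 1484 higher and 2352 lower in the Noggin-deficient samples, and 426 of them changed over 2-fold (146 higher and 280 lower). These genes had already been selected for a difference between the same samples, so the counts describe the selected set and not the transcriptome. Of the calls 38.7% were higher, against 53.9% when the libraries were scaled by median-of-ratios factors over the listed genes. That scaling shifted the median log2 change of all genes by 0.26. The share was 48.7% after removal of a trend on transcript length. Under these settings the sign turned for 239 and 475 of the genes called, mostly without a call in the new direction. Of the 2760 and 2696 calls under them, 2756 and 2595 were among the 3836 with the same sign. The trend on transcript length was steep: 67.1% of the genes in the shortest eighth were higher in the Noggin-deficient samples and 6.2% in the longest. Against a 1.5-fold change, 569 genes passed, 165 higher and 404 lower. Many members of the gene lists were not analysed here: those tested were 11 of 18 BMP response, 49 of 66 sarcomere, 7 of 24 differentiation, 7 of 31 progenitor, 8 of 21 bone, 5 of 22 endothelial and 17 of 76 ribosomal protein genes.

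**Figure D2:**
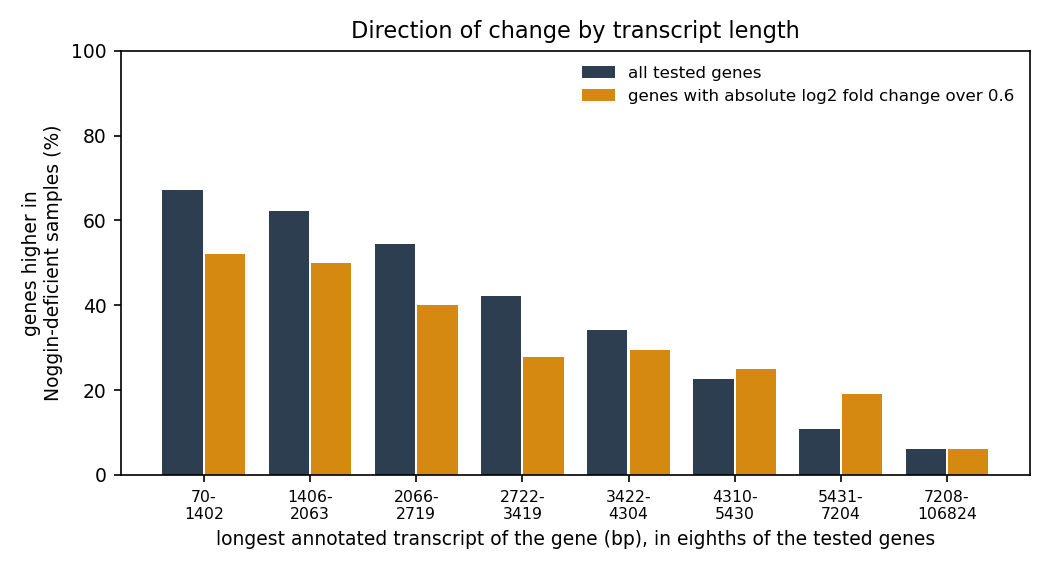
Percent of genes higher in the Noggin-deficient samples in each eighth of 3742 genes with a known transcript length. The eighths run from the shortest (70 to 1402 bp) to the longest (7208 to 106824 bp). Of these genes 3730 were tested, and the few others carried the change of another gene with a longer symbol. Dark bars are all these genes, which go from 67.1% to 6.2%. Orange bars are those with an absolute log2 change over 0.6, which go from 52.1% to 6.1%.

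The largest rises named by the rule included plasma protein and fat cell genes. Alb, the gene of albumin, went from 0.38 ± 0.0141 (SD, n = 2) to 39.5 ± 0.623 (SD, n = 3), Afp, the gene of alpha-fetoprotein, from 0.525 ± 0.00707 (SD, n = 2) to 29.8 ± 0.737 (SD, n = 3), and Apoa1, of apolipoprotein A-I, from 0.285 ± 0.148 (SD, n = 2) to 10.4 ± 0.371 (SD, n = 3). Their log2 changes were 5.98, 5.28 and 4.34. Adipoq, the gene of the fat cell hormone adiponectin, followed with 3.09, then Gpd1, a glycerol phosphate dehydrogenase, with 2.63, the ribosomal RNA precursor Rn45s with 1.47, the embryonic globin gene Hbb-y with 1.42 and the transferrin gene Trf with 1.39. The largest falls included genes of the outer epidermis. Hrnr, of the cornified layer, went from 22.4 ± 0.332 (SD, n = 2) to 1.21 ± 0.0586 (SD, n = 3), a log2 change of -3.95. Orm1, Psca, Lce3f, Krt13, Alox12b, Aox4 and Stfa3 had log2 changes from -3.70 to -2.90. Alb, Afp and Apoa1 are characteristic of liver, and Lce3f and Alox12b of the epidermal barrier.

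Genes of contractile muscle fell. Of 49 tested sarcomere and excitation-contraction genes, 47 fell and 2 rose, with a median log2 change of -0.56 and the same 49 passing when adjusted over the list alone (camera adjusted p = 1.7e-06, and adjusted p = 0.28 with an estimated correlation). Mybpc1, a myosin-binding protein, went from 181.4 ± 1.36 (SD, n = 2) to 94.3 ± 1.35 (SD, n = 3), and Ldb3, a Z-disc protein, from 63.3 ± 0.509 (SD, n = 2) to 33.9 ± 0.188 (SD, n = 3). Ckm, the muscle creatine kinase, had a log2 change of -1.08, and the mitochondrial kinase gene Ckmt2 one of -1.96. Actn3, an alpha-actinin of fast fibres, rose by 0.70 and Mb, of myoglobin, by 0.48. The embryonic myosin gene Myh3 went from 777.8 ± 4 (SD, n = 2) to 602.3 ± 17.6 (SD, n = 3), a log2 change of -0.37 (adjusted p = 5.2e-05) that was -0.04 (adjusted p = 0.29) after removal of the length trend, and which did not pass against a 1.5-fold change. The sarcomere list as a whole kept its fall after that removal, with a median of -0.50 (camera adjusted p = 4.7e-10). Mybpc1 was then at -0.76 and Ldb3 at -0.61. Median-of-ratios scaling brought the median of the sarcomere list to -0.29 and the change of Myh3 to -0.10 (adjusted p = 0.049), and upper-quartile scaling brought them to -0.36 and -0.17. Transcripts of liver, blood and neurons were higher and those of epidermis lower in the same Noggin-deficient samples.

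The 7 tested genes of myogenic differentiation and fusion fell, with a median log2 change of -0.53 and 7 calls adjusted over the list alone (camera adjusted p = 0.023, and adjusted p = 0.28 with an estimated correlation). Myf6, a muscle regulatory factor, went from 16.8 ± 0.481 (SD, n = 2) to 8.74 ± 0.102 (SD, n = 3), and Srl, a calcium-binding protein of the sarcoplasmic reticulum, had a log2 change of -0.60. The call of this list was lost after removal of the length trend (adjusted p = 0.053) and by Fisher's exact test of direction (adjusted p = 0.12). Of 7 tested muscle progenitor genes, 6 fell and 1 rose (median -0.35, adjusted p = 0.36). Vcam1, an adhesion molecule, rose by 0.37, and Notch1, a receptor, had a log2 change of -0.35 that turned to 0.06 after removal of the length trend. The 6 tested genes of the neuromuscular junction fell (median -0.51, adjusted p = 0.076, and 0.046 with no filter on low values), with log2 changes of -0.54 for Erbb3, a neuregulin receptor that is also on the Schwann cell and neuron list, and -0.55 for Utrn, a relative of dystrophin. The 7 and 6 members of these lists passed adjusted over the list alone. Under median-of-ratios scaling the medians of the differentiation, progenitor and junction lists were -0.26, -0.08 and -0.24, and after removal of the length trend -0.25, -0.08 and -0.24. The same settings gave -0.27 and -0.21 for Erbb3, -0.28 and -0.11 for Utrn, -0.33 and -0.32 for Srl and 0.64 and 0.57 for Vcam1, and median-of-ratios scaling gave -0.08 for Notch1. Srl, Vcam1, Notch1, Erbb3 and Utrn did not pass against a 1.5-fold change.

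Bone genes rose. The 8 tested members had a median log2 change of 0.62, and 8 passed adjusted over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.28 with an estimated correlation). Alpl, the alkaline phosphatase of mineralising tissue, went from 9.55 ± 0.198 (SD, n = 2) to 15.8 ± 0.577 (SD, n = 3), and Mmp13, a collagenase, from 10.1 ± 0.0354 (SD, n = 2) to 15.3 ± 0.359 (SD, n = 3). Sp7, an osteoblast transcription factor, rose by 0.53 and Spp1, of osteopontin, by 0.39. Distal limb genes were higher in the same samples. Against a 1.5-fold change, Alpl (adjusted p = 0.051) and Mmp13 (adjusted p = 1) did not pass.

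The lists of other connective tissues held members that went both ways and were not called by camera. Fry, which compares a list with no other genes, called each of them (adjusted p from 0.00019 to 0.00069). Fry called 23 of the 24 lists tested, over genes already selected for a difference between these samples. Its calls therefore say nothing particular about these lists. Of 15 tested cartilage genes 4 rose, among them Pth1r at 0.39, and 11 fell, among them Col11a1 at -0.41 (median -0.35, adjusted p = 0.44). Of 8 tendon genes 1 rose and 7 fell (median -0.30, adjusted p = 0.14), Thbs2 at -0.49 and Col12a1 at -0.45. Of 22 fibroblast genes 8 rose, Sfrp1, a Wnt antagonist, by 0.82, and 14 fell, Dpt, of dermatopontin, with -0.73 (median -0.28, adjusted p = 0.85), the median turning to 0.00 after removal of the length trend. Of 6 smooth muscle and pericyte genes 1 rose and 5 fell (median -0.41, adjusted p = 0.26), among them Ndufa4l2 at -0.77 and Des at -0.43. The 15, 8, 22 and 6 members were also called adjusted over the list alone. Under median-of-ratios scaling the medians of the cartilage, tendon, fibroblast and smooth muscle lists were -0.08, -0.03, -0.01 and -0.14, and the changes of Pth1r, Col11a1, Thbs2, Col12a1, Dpt, Ndufa4l2 and Des were 0.66, -0.14, -0.22, -0.17, -0.45, -0.50 and -0.15. After removal of the length trend the medians of the cartilage, tendon and smooth muscle lists were -0.02, -0.18 and -0.19, and the change of Thbs2 was -0.17. Pth1r, Col11a1, Thbs2, Col12a1 and Des did not pass against a 1.5-fold change, and after removal of the length trend Col11a1 (-0.04, adjusted p = 0.25) and Col12a1 (-0.01, adjusted p = 0.64) no longer passed.

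Adipogenic and brown fat genes parted. Of 15 tested, 7 rose and 8 fell, and 15 passed adjusted over the list alone. Adipoq went from 1.46 ± 0.332 (SD, n = 2) to 14.3 ± 0.870 (SD, n = 3) and Fabp4, a fatty acid binding protein, from 78.3 ± 0.962 (SD, n = 2) to 171.6 ± 3.85 (SD, n = 3). Pparg, a regulator of fat cell formation, rose by 0.90 and Plin1, a lipid droplet protein, by 2.12. Dgat2, an enzyme of triglyceride synthesis, had a log2 change of -1.20, Ppara one of -0.80 and Cidea one of -0.39. Liver genes, which include further genes of lipid transport, were higher in the same samples. The median was -0.28, the mean 0.31 and the camera direction up (adjusted p = 0.21), and the median was -0.10 under median-of-ratios scaling and turned to 0.36 with no filter on low values, to 0.39 with a stricter filter and to 0.04 after removal of the length trend.

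YAP target and mechanical response genes went both ways, 4 rising and 8 falling of 12 tested (median -0.28, adjusted p = 0.88), the median being -0.02 under median-of-ratios scaling, -0.08 under upper-quartile scaling and turning to 0.05 after removal of the length trend. Ankrd1, a YAP target also induced in stressed muscle, went from 4.23 ± 0.148 (SD, n = 2) to 8.53 ± 0.546 (SD, n = 3), a log2 change of 0.97. Amotl1, an angiomotin, had a log2 change of -0.31, which was -0.04 under median-of-ratios scaling and turned to 0.08 after removal of the length trend. Of 7 Notch signalling genes 4 rose and 3 fell (median 0.38, adjusted p = 0.46, and a median of 0.64 under median-of-ratios scaling and 0.24 after removal of the length trend), with the effector gene Hey1 rising by 0.55 and Nrarp, a feedback inhibitor, at -0.40. Of 4 TGF-beta genes, too few for the set test, 1 rose and 3 fell (median -0.44), Bhlhe40 at -0.64 and Ltbp2 at -0.60. The 5 tested genes of the S and G2/M phases, out of 36 on the list, rose (median 0.38, or 0.65 under median-of-ratios scaling, camera adjusted p = 0.0042, and adjusted p = 0.28 with an estimated correlation), Mcm7, of the replicative helicase, by 0.39 and Birc5, of mitosis, by 0.47. All members of these lists were called adjusted over the list alone. Erythroid genes were higher in the same samples. Under median-of-ratios scaling Nrarp, Bhlhe40, Ltbp2, Mcm7 and Birc5 changed by -0.13, -0.37, -0.35, 0.66 and 0.73, and Ltbp2 by -0.26 after removal of the length trend. Amotl1, Hey1, Nrarp, Bhlhe40, Ltbp2, Mcm7 and Birc5 did not pass against a 1.5-fold change.

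Markers of other cell types that the dissected tissue could hold moved with the genotype. The 20 tested epidermis genes fell, with a median log2 change of -1.0 (camera adjusted p = 4.7e-06, and adjusted p = 0.22 with an estimated correlation), and Lor, of loricrin, went from 366.2 ± 23.8 (SD, n = 2) to 49.1 ± 1.52 (SD, n = 3). The 11 erythroid genes rose, with a median of 0.61 (camera adjusted p = 0.00034, and adjusted p = 0.22 with an estimated correlation), Hbb-y going from 53.2 ± 3.52 (SD, n = 2) to 142.7 ± 5.12 (SD, n = 3). Of 5 endothelial genes 4 rose, Cldn5 by 0.65 (adjusted p = 0.25 against a 1.5-fold change), and 1 fell (median 0.49, or 0.76 under median-of-ratios scaling, camera adjusted p = 0.027, and adjusted p = 0.32 with an estimated correlation; Fisher's exact test of direction gave 0.15). Of 16 Schwann cell and neuron genes 10 rose and 6 fell (camera adjusted p = 0.047, and adjusted p = 0.28 with an estimated correlation). Within that list the neuronal intermediate filament gene Prph went from 0.845 ± 0.0354 (SD, n = 2) to 5.76 ± 0.273 (SD, n = 3), while glial genes went both ways, with log2 changes of -0.25 for Sox10, -0.39 for Mbp, 0.60 for Fabp7 and 0.41 for S100b. The call of that list was lost without Noggin-deficient replicate 1 (adjusted p = 0.058), without wild type replicate 2 (adjusted p = 0.051) and under several other settings.

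Of 6 genes of macrophages and other white blood cells 4 rose and 2 fell (median 0.63, or 0.24 after removal of the length trend, adjusted p = 0.31), the mast cell protease gene Mcpt4 at -0.81 and the myeloid gene Mpo rising by 1.83. Of 14 limb position genes 11 rose and 3 fell, with a median of 0.53 (camera adjusted p = 0.004, and adjusted p = 0.28 with an estimated correlation). Those that rose included the distal genes Hoxa13, from 0.26 ± 0.0283 (SD, n = 2) to 1.46 ± 0.105 (SD, n = 3), and Hoxd13, with a log2 change of 2.01, and those that fell were Hoxc6, Hoxc8 and Hoxc9. In each of these 6 lists of other cells and position, every tested member was called, also adjusted over the list alone. As 3836 of the 3913 tested genes were called, this says nothing particular about the lists. The sex-linked list had no tested member.

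Of the lists of RNA quality, the 17 tested ribosomal protein genes rose, with a median log2 change of 0.39 (camera adjusted p = 4.7e-06, and adjusted p = 0.32 with an estimated correlation). Rpl11 went from 192.5 ± 6.76 (SD, n = 2) to 251.7 ± 5.07 (SD, n = 3). After removal of the length trend, the median of that list was 0.07 (adjusted p = 0.25; 0.66 under median-of-ratios scaling) and the change of Rpl11 0.03 (adjusted p = 0.39; 0.66 under median-of-ratios scaling). The 7 immediate early and heat shock genes fell (median -0.73, or -0.46 under median-of-ratios scaling, camera adjusted p = 0.027, and adjusted p = 0.28 with an estimated correlation; Fisher's exact test of direction gave 0.12), Hspa1a, an inducible chaperone gene, going from 22.9 ± 0.445 (SD, n = 2) to 10 ± 0.193 (SD, n = 3). The 17 and 7 members were also called adjusted over the list alone. Rn45s varied within the groups, with 1412, 1251 and 3362 in the Noggin-deficient and 824 and 518 in the wild type libraries (log2 change 1.47, SE 0.405, adjusted p = 0.0087). Without wild type replicate 2 its change was 1.14 (adjusted p = 0.067). Neither Rpl11 nor Rn45s passed against a 1.5-fold change.

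**Figure D3:**
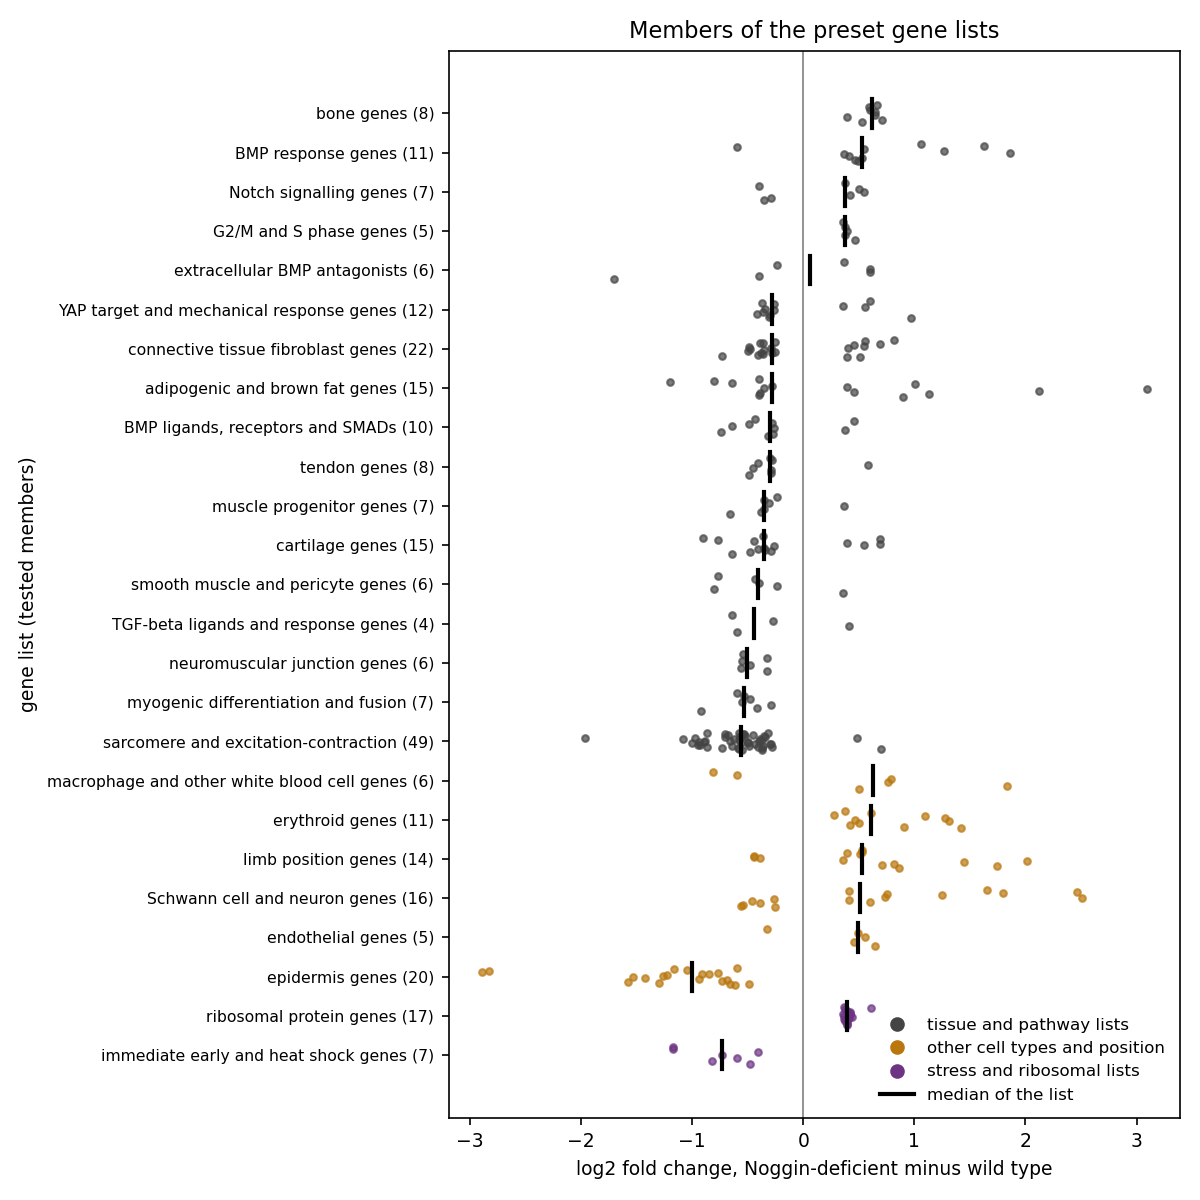
Log2 fold change, Noggin-deficient minus wild type, of each tested member of the gene lists written before the data were examined, with 1 point per gene, a black bar at each median and the number of tested members in parentheses. Points leave a gap around 0 because the listed genes had been selected for a difference; the median is -0.56 for sarcomere genes, -1.0 for epidermis genes, 0.53 for BMP response genes and 0.61 for erythroid genes.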

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

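Centring on the gap, removal of the length trend and Fisher's test of direction were chosen after seeing the data; the other settings were planned. The planned DESeq2, limma-voom and edgeR fits were not run, since they need counts. Of the values of named genes under the alternatives, 1060 kept their direction and their side of the threshold, 35 no longer passed and 2 turned. Of those of gene lists, 457 kept both, 28 lost and 12 gained their call, and 6 turned. The 3836 calls became 3831 to 3841 with other pseudocounts, 2760 under median-of-ratios, 3099 under upper-quartile and 3546 under equal-total scaling, and 3583 to 3780 when each library was left out, where a lone wild type library was assumed to vary like the others. The scalings shifted the median log2 change by 0.26, 0.19 and 0.12. Under a pseudocount of 1, 218 genes changed over 2-fold, in place of 426, because a larger pseudocount shrinks the changes of low genes. Median-of-ratios scaling left 1272 lower genes in place of 2352, by centring the changes of genes that had been selected for a difference. The test against a 1.5-fold change called 569 genes, 165 higher and 404 lower, being stricter by construction. Removal of the length trend left 1383 lower genes. The lists called numbered 12, 0 with an estimated correlation and 23 by fry, and 11 or 12 when each library was left out; the 0 stands beside 3837 genes at an unadjusted p under 0.05 in limma. Medians that turned were those of the BMP antagonists (-0.24) and adipogenic genes (0.36) with no filter, of adipogenic genes (0.39) with a stricter filter, and of YAP target (0.05), fibroblast (0.00) and adipogenic genes (0.04) after removal of the length trend, as did Notch1 (0.06) and Amotl1 (0.08). The filters changed which members were tested; for the others the cause was not tested.

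The labels give both groups replicate numbers 1 and 2, but the samples share only a number. With the replicate block, 3772 genes were called (1468 higher and 2304 lower, 430 over 2-fold) and 11 lists. The differences between replicates 1 and 2 in the groups correlated at r = -0.152 over 3305 genes. Depth is unknown, so what it limits could not be computed.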

Other observations

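The liver, sympathetic, epidermal layer, mast cell and gene family lists used here were written after values had been seen, and so were the tests of skin share and both tests on liver genes; the tests of transcript length within lists, of uneven selection and of epidermis after removal of the length trend were set before their results were seen. Genes of hepatocytes and plasma proteins rose in the Noggin-deficient samples, with 31 of 31 tested members of the list called, a count that restates the rise the list was written from. Besides Alb, Afp and Apoa1, Ahsg, of fetuin, went from 0.015 ± 0.0212 (SD, n = 2) to 5.71 ± 0.443 (SD, n = 3) and Ttr, of transthyretin, from 0.14 to 4 ± 0.266 (SD, n = 3). Serpina1a, Serpina1b, Serpina1c, Serpina1d, Fgb and Fabp1 were listed at 0 in both wild type libraries, and the Serpina1 genes are near-identical copies whose values are uncertain. Of 25 tested genes of sympathetic neurons and chromaffin cells, 22 rose and 3 (Ddc, Gata3 and Ret) fell. Th, of tyrosine hydroxylase, went from 0.02 ± 0.0141 (SD, n = 2) to 1.51 ± 0.173 (SD, n = 3), and Dbh, which makes noradrenaline, from 0.56 ± 0.0424 (SD, n = 2) to 3.45 ± 0.197 (SD, n = 3). Gata3, Hand1 and Hand2 of that list also stand in the BMP response list.

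The 9 tested mast cell genes fell, with a median log2 change of -0.60, and Cma1, of chymase, went from 212.5 ± 8.41 (SD, n = 2) to 140.4 ± 3.18 (SD, n = 3). The 9 basal epidermis genes fell (median -0.49), and of 20 genes of the cornified envelope and granular layer 19 fell and Tchh was not called (median -1.83). Of 13 tested genes of mitochondrial ribosomal proteins, 13 were higher (median 0.42), with no set test. Their median transcript length was 2220 bp, in an eighth where 54.4% of the genes were higher. The cytosolic ribosomal list came to 0.07 once the length trend was removed, which moves typical short genes that rose towards 0 by construction. Of 21 genes whose symbols are Col followed by a digit, nearly all collagens, 18 fell, 2 rose and 1, Col4a6, was not called (median -0.35), with Col1a1 going from 4137 ± 67.0 (SD, n = 2) to 3115 ± 8.20 (SD, n = 3). Their median transcript length was 6119 bp, in an eighth where only 10.9% of the genes were higher. Col11a1 and Col12a1 lost their calls once the length trend was removed (-0.04 and -0.01). That removal moves typical long genes that fell towards 0 by construction, so it does not show the cause. Of 80 solute carrier genes 28 rose, 50 fell and 2 were not called, and of 49 zinc finger genes 17 rose, 29 fell and 3 were not called. The short non-coding gene Mir6236 had values of 430, 259 and 321 in the Noggin-deficient and 146 and 138 in the wild type libraries.

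The share of genes higher in the Noggin-deficient samples fell with transcript length. The Spearman correlation of log2 change with length was -0.27 over 3742 genes, and -0.21 given GC content, across genes that are not independent. Of these genes 3730 were tested, and the few others carried the change of another gene with a longer symbol. Uneven selection of small rises and falls is argued against, since 6.1% of genes in the longest eighth were still higher among those with an absolute log2 change over 0.6, against 52.1% in the shortest. A length bias between the RNA or the libraries of the groups may contribute, since the trend was also present within gene lists (median Spearman correlation -0.27, 12 of 13 lists negative), although only that of the zinc finger genes passed a permutation test after adjustment (adjusted p = 0.012) and some lists share genes. A lower output of long genes with the genotype stays open and was not tested.

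Epidermis genes were lower in the Noggin-deficient samples, with log2 changes of -0.61 for Krt5 and -0.49 for Krt14 of the basal layer and of -1.58 for Krt10 and -2.89 for Lor of the upper layers. A length bias is argued against as the whole cause. The epidermis list had a median transcript length of 2146 bp, in an eighth where the median log2 change was 0.36. The median of the list was still -1.0 after the length trend was removed. Medians of the eighths went only from 0.4 to -0.37, so that removal could not have brought the list near 0 and decides nothing by itself. A smaller share of skin as the whole cause is also argued against, since cornified-layer genes fell further than basal genes by a difference of -1.41 in mean log2 change, against a standard deviation of 0.032 between libraries of a group. Both layer lists were written after values had been seen, and the spread between libraries may be technical. Less skin together with a less advanced epidermis, a difference in embryo stage, or an effect of the genotype on the epidermis stay open as hypotheses, and none of these was tested.

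Liver genes were higher in the Noggin-deficient samples, with Alb at 39.5, Afp at 29.8, Trf at 19.8 and Apoa1 at 10.4. A different amount of liver RNA in each library is argued against, since the summed values were 171, 173 and 174 in the Noggin-deficient libraries (coefficient of variation 0.77%) and 21.8 and 20.1 in wild type. Liver tissue RNA in a source shared by the Noggin-deficient libraries may contribute. Fetal liver makes red blood cells, and 100% of the tested members of the preset erythroid list were higher. Those were 11 of the 22 genes on that list, taken from tables that hold only genes selected for a difference. But the limb's own blood also holds these transcripts, and the largest rise on the list was of the embryonic globin gene Hbb-y (1.42). The erythroid rise therefore does not tell the sources apart. Fat and other limb cells also make Trf, C3 and Rbp4, and Orm1, a plasma protein gene left off the list, went the other way (log2 change -3.70). Expression of these genes in the limb with the genotype stays open and was not tested.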
